A study of Mus musculus with 6 samples.

How the data were processed

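RNA-seq gene counts of mouse small-intestinal organoids were analysed. Organoids are small epithelial structures grown from crypts in a gel, here from the proximal small intestine. The mouse line carried a human YAP gene and a red fluorescent histone under a promoter that doxycycline switches on (TetON-hYAP/H2B-mCherry). YAP is the transcriptional coactivator at the end of the Hippo pathway, and the series' design text describes the transgene as a constitutively active mutant. Doxycycline was given at 1 µg/ml for 48 h from the time of passaging, per the labels' protocols, and the control organoids had none. There were 3 libraries in each of the 2 groups, grouped by the treatment given in the labels.

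The deposited table held whole-number read counts per gene for the 6 libraries, with 24594 Entrez gene IDs. Per the labels' protocols, total RNA was taken with a column kit, libraries were made with an Illumina TruSeq RNA kit and sequenced on a NextSeq. The genome build was mm10 per the submitters' processing notes. The aligner, the counting tool, the gene annotation, the use of strand and any filter were not given in the sources used here, so counts of overlapping genes, antisense genes and near-identical copies are uncertain. Symbols, positions and gene types came from RefSeq's gene table of GRCm38.p6, the assembly that mm10 stands for, which matched 24570 of the IDs. The other 24 had no symbol and were kept under their IDs, in library sizes and tests, where they passed edgeR's expression filter. They held 2.88 to 4.43% of the counts of a library, nearly all in 1 ID (2.87 to 4.42%).

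Counts were tested with edgeR 4.0.16 (R 4.3.3). Genes passed edgeR's expression filter by group, which left 12909, and libraries were scaled by TMM. The test was the robust quasi-likelihood F-test of doxycycline against control, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A gene described as having risen, fallen or changed passed that threshold. CPM, on the usual counts-per-million scale with TMM-scaled library sizes, are given as mean ± SD over the 3 libraries of a group. The TMM factors were 1.169, 1.163 and 1.166 in the control libraries and 0.879, 0.852 and 0.843 in the doxycycline libraries. The median log2 fold change of all genes was -0.08 with TMM and -0.53 with total counts as the only scaling, so directions are relative to the TMM scale.

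Before the data were examined, 26 gene lists, the rule for naming genes, the tests and their alternatives were fixed. The lists covered YAP/TAZ-TEAD targets, Hippo pathway components, fetal and regenerating epithelium, crypt base columnar stem cells, Wnt targets, Paneth, goblet, enteroendocrine and tuft cells, enterocytes and proliferation. They also covered p53 targets, EGFR ligands with ERK feedback genes, AP-1, NF-kB, interferon-stimulated genes, MHC class II, adhesion with matrix and actin genes, cholesterol synthesis, the integrated stress response, oxidative phosphorylation, and mesenchymal, immune, endothelial and gastric markers. The list of mitochondrially encoded genes was not analysed here. Lists with at least 5 measured members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation between genes 0.01), adjusted over the 20 lists tested. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in one direction, were run beside it.

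Genes were named by a rule with 3 parts. It took 16 fixed genes and the 10 largest fitted rises and 10 largest fitted falls among changed genes with a mean of at least 5 CPM, no overlap between the groups and a symbol that was not a predicted model. It also took up to 4 members of each list with the smallest adjusted p. The rule gave 119 genes. A further 35 genes were singled out after their values were seen, and the text says so where they appear. Some of these genes are not reported here one by one, though they stayed in the list tests and counts. Where all libraries of a group held 0 counts, a fold is a lower bound computed against 3 counts over that group. Where a group held 1 to 3 counts, the ratio is given with its 95% exact binomial interval. Bounds and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

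The alternatives were RLE factors, total counts, TMM without the 20 highest genes, no low-count filter, a filter of 10 counts in 3 samples, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, a threshold of 0.01 and edgeR's test against a 2-fold change. After the data were seen, 3 more were added. They were the removal of a trend with transcript length within each library, limma-voom with library quality weights, and gene families defined by symbol stems. The trend was fitted to each library's deviation from the mean of all 6 libraries. Its removal can therefore also take out differences between the groups that go with length. Principal components were computed on log2 CPM. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

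The gene tests, the list tests and the removal of the length trend were tried on counts simulated for doxycycline against control. In these, 50 genes were changed at each of 4 fold sizes. Over 12716 simulated genes tested, edgeR recovered 6% of the genes changed 1.5-fold, 14% at 2-fold, 88% at 4-fold and 98% at 8-fold, with 2.83% false calls. In the same simulation DESeq2 gave 19.8% false calls over 12909 genes and limma-voom 1.94%. All simulated libraries shared the dispersions fitted to the 6 real ones, and none stood apart as control replicate 3 did in the data. The rates of recovery and of false calls may therefore not hold for the data. None of 40 simulated lists without a change was called by camera or fry. The simulated genes were drawn independently of each other, so this does not show how often lists of correlated genes are called. Total counts ran from 8533452 to 16803062 per library. The libraries are labelled as replicates, and the growth protocol, which also covers other samples of the series, speaks of 1 adult animal per sample. The labels do not say that the 3 cultures of a group came from different animals, so p-values measure the spread between these libraries, which may in part be technical.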

Results

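Gene expression was measured by RNA-seq in adult mouse intestinal organoids that carried a doxycycline-inducible, constitutively active human YAP, with the transgene off (3 control libraries) or induced for 48 h (3 doxycycline libraries). The control libraries held 14643817, 11182703 and 8533452 counts and the doxycycline libraries 11258768, 12698043 and 16803062. The comparison asks which genes differ when active YAP is induced. No sample had doxycycline without the transgene, so effects of the drug and of YAP were not separated.

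With doxycycline, all measured markers of crypt base stem cells and Paneth cells and 12 of 13 of goblet cells fell, while most YAP/TAZ-TEAD targets and fetal and regenerative markers and several enterocyte genes rose. Of these lists, that of stem cells alone was called with an estimated correlation between members. The stem cell marker Olfm4 went from 3965 ± 676 to 6.07 ± 0.685 CPM (SD, n = 3 per group) and the R-spondin receptor gene Lgr5 from 204.0 ± 59.5 to 0.995 ± 0.391 CPM. The Paneth cell lysozyme Lyz1 went from 2607 ± 1005 to 31.9 ± 1.07 CPM. In the other direction, the matricellular gene Ccn2 rose from 3.46 ± 0.119 to 144.3 ± 4.68 CPM, the cytokine gene Il33 from 10.3 ± 1.96 to 521.4 ± 38.4 CPM and the keratin gene Krt20 from 99.0 ± 2.05 to 2406 ± 197 CPM.

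Of 12909 genes tested with edgeR, 5850 (45.3%) had an adjusted p under 0.05, with 2800 higher and 3050 lower with doxycycline. Of these, 1976 were at least 2-fold higher and 2262 at least 2-fold lower. The CPM of the groups did not overlap for 7913 genes (61.3%), where chance gives 10%. With total counts as the only scaling, 1747 genes were higher and 5131 lower, so 25.4% of the calls were higher against 47.9% with TMM. Control replicate 3 stood apart from the other control libraries, and 9286 genes were called without it (4632 higher, 4654 lower). Without doxycycline replicate 2 the count was 3862 and without doxycycline replicate 3 it was 3836.

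**Figure D1:**
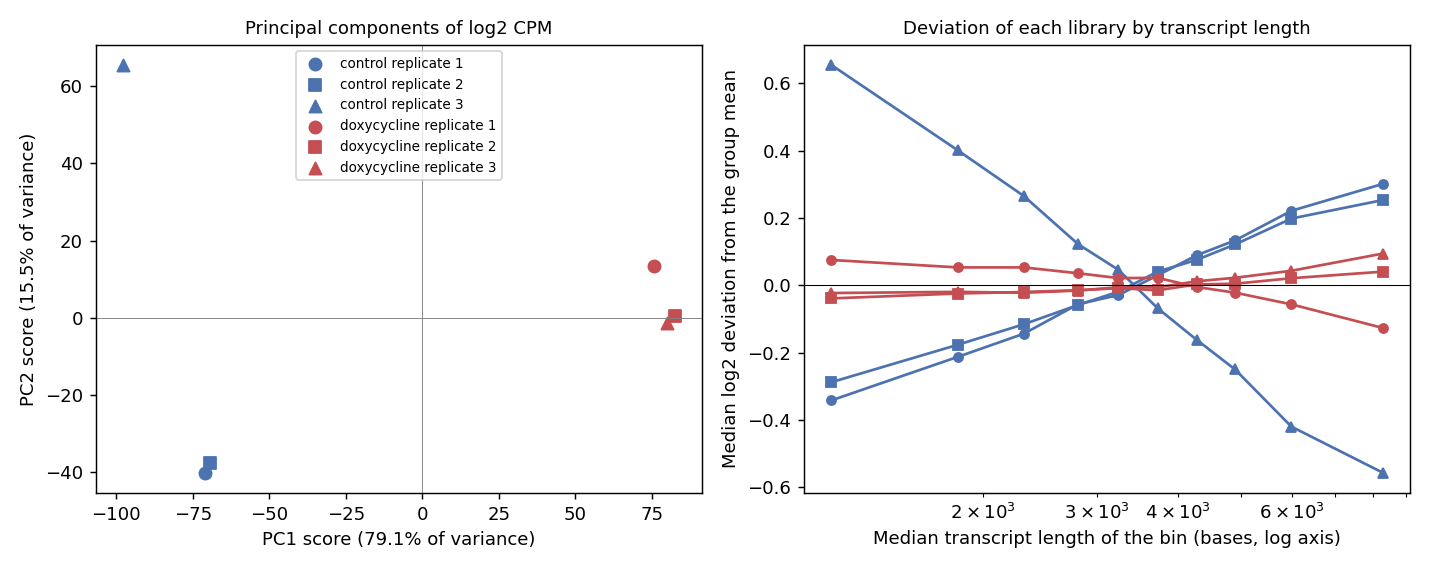
Left, principal component scores of the 6 libraries on log2 CPM (PC1 79.1% and PC2 15.5% of the variance; blue, control; red, doxycycline); the doxycycline libraries sat between 75.62 and 82.45 on PC1 and the control libraries between -97.65 and -69.25, and control replicate 3 lay at 65.5 on PC2 against -40.22 and -37.68 for the other control libraries. Right, median log2 deviation of each library from its group mean in 10 bins of transcript length (bases, log axis); control replicate 3 ran from 0.65 in the shortest bin to -0.56 in the longest.

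The mouse Yap1 gene (Entrez 22601, chromosome 9, 7931999 to 8004638, GRCm38.p6) had 230.6, 236.5 and 156.4 CPM in the control libraries and 142.4, 149.0 and 145.9 CPM with doxycycline. Its log2 fold change was -0.51 (SE 0.197, edgeR adjusted p = 0.0707), which did not pass the threshold; without control replicate 3 it was -0.67 (adjusted p = 1.28e-07). The transgene is a human sequence and was not analysed here, so the mouse row does not check the labels. With the aligner not known, the mouse row may or may not hold some reads of the transgene. Of 18 measured YAP/TAZ-TEAD target genes, 15 rose and 1 fell, with a median log2 fold change of 2.62 (camera adjusted p = 9.53e-08; adjusted p = 0.0814 with an estimated correlation). Ccn1 (chromosome 3, 145646971 to 145649985), a secreted matricellular protein, rose from 9.96 ± 1.34 to 114.9 ± 5.22 CPM, a log2 change of 3.53 (SE 0.177, adjusted p = 5.12e-05). Ccn2 (chromosome 10, 24595442 to 24598683) rose by 5.38 on the log2 scale (SE 0.167, adjusted p = 2.25e-05). Nt5e, an ectonucleotidase, rose by 6.92 and Asap1, an Arf GTPase-activating protein, by 3.26. Ankrd1 had 2 counts over the control libraries and 256 with doxycycline, a ratio of 147 after scaling (95% interval 40.3 to 1221). Both control counts were in control replicate 3, without which Ankrd1 was at least 73.7-fold higher, and without control replicate 1 the ratio was 84.2. Rbms3, singled out after its values were seen, was the member that fell (5.29 ± 0.356 to 1.70 ± 1.11 CPM); its call was lost without control replicate 1 (adjusted p = 0.0529), doxycycline replicate 1 (0.0884) or doxycycline replicate 2 (0.0763), and its log2 change of -1.60 was -2.29 without doxycycline replicate 3.

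Of 20 genes of the Hippo pathway itself, 7 rose and 2 fell (median log2 fold change 0.41, camera adjusted p = 0.0281; adjusted p = 0.549 with an estimated correlation). The list was not called without control replicate 3 (adjusted p = 0.131, 11 rose and 5 fell) or with the length trend removed (adjusted p = 0.0519), and its median was -0.03 with total counts as the scaling. The DNA-binding partners of YAP went both ways, as Tead4 rose from 3.15 ± 0.985 to 28.2 ± 1.61 CPM and Tead2 fell from 14.8 ± 4.29 to 0.543 ± 0.235 CPM. Wwc2, a scaffold of the kinase cascade, rose from 9.75 ± 5.90 to 237.2 ± 24.1 CPM and Amotl1, an angiomotin family member, from 3.56 ± 0.42 to 24.2 ± 1.21 CPM. The other member that fell was Amot (147.2 ± 65.6 to 68.2 ± 7.10 CPM), singled out after its values were seen. With control replicate 1 or 2 or any doxycycline library left out, or with limma-voom, the adjusted p of Amot was 0.0657 to 0.139.

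Of 14 measured markers of fetal and regenerating epithelium, 13 rose and 1 fell (median log2 fold change 2.75, camera adjusted p = 4.35e-06; adjusted p = 0.0676 with an estimated correlation). Ly6a, which encodes the surface protein Sca-1, rose from 13.8 ± 8.60 to 107.4 ± 19.97 CPM (log2 change 2.97, SE 0.435, adjusted p = 0.00194; 3.61 without control replicate 3). Clu, a secreted chaperone, rose from 22.4 ± 3.79 to 87.7 ± 5.59 CPM, and the keratin gene Krt7 from 125.4 ± 18.3 to 3232 ± 262 CPM. Igf2bp1, an RNA-binding protein of fetal tissues, rose from 0.303 ± 0.131 to 31.4 ± 1.48 CPM. Hmga2, a chromatin protein of embryonic tissues, went the other way, from 45.01 ± 4.98 to 1.97 ± 0.145 CPM.

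**Figure D2:**
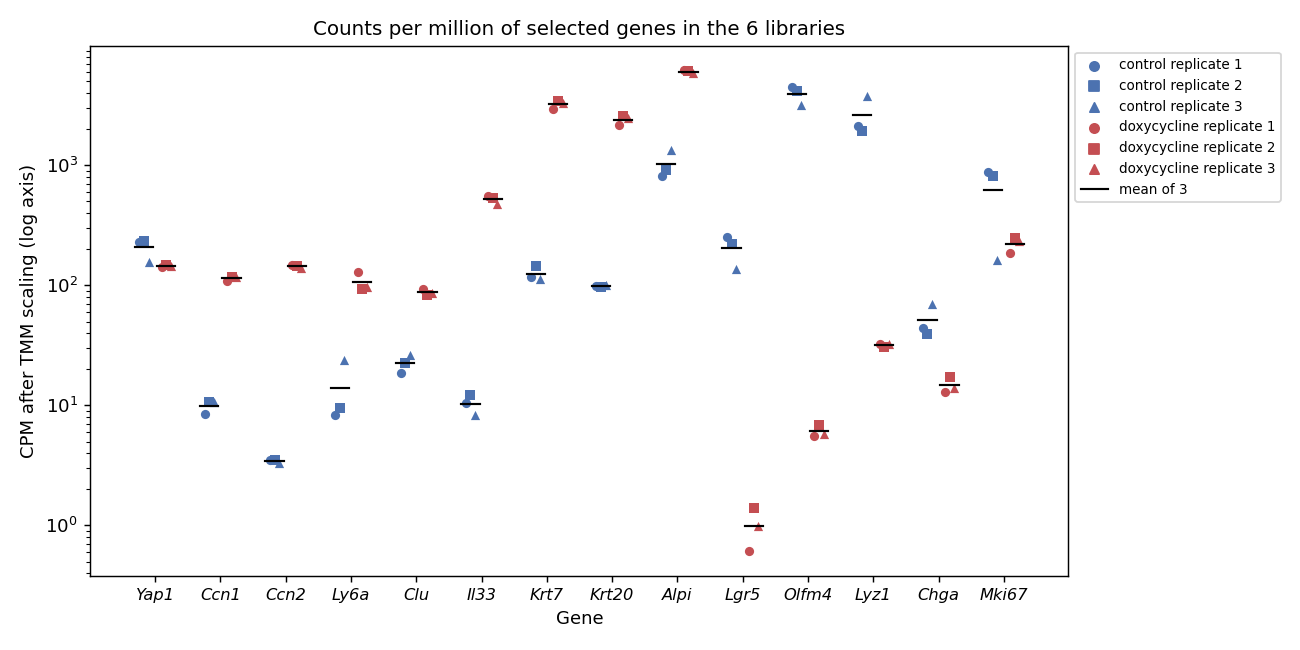
CPM after TMM scaling (log axis) of 14 genes in the 6 libraries (blue, control; red, doxycycline; symbols, replicates 1 to 3; bars, means of 3). Ccn1, Ccn2, Ly6a, Clu, Il33, Krt7, Krt20 and Alpi lay higher in all 3 doxycycline libraries and Lgr5, Olfm4, Lyz1 and Chga lower, while Yap1 and Mki67 had adjusted p of 0.0707 and 0.0727.

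All 14 markers of crypt base columnar stem cells fell (median log2 fold change -4.36, camera adjusted p = 1.18e-09; adjusted p = 0.0447 with an estimated correlation). Lgr5 (chromosome 10, 115450314 to 115587780) fell by 7.66 on the log2 scale (SE 0.403, adjusted p = 5.89e-05) and Olfm4 (chromosome 14, 80000302 to 80023141) by 9.35 (SE 0.274, adjusted p = 2.25e-05). Ascl2, a transcription factor of stem cells, fell from 52.4 ± 10.6 to 1.18 ± 0.101 CPM, the RNA-binding protein gene Msi1 from 39.97 ± 7.01 to 0.417 ± 0.189 CPM, and Smoc2 from 241.8 ± 43.1 to 15.7 ± 0.963 CPM. Of 11 measured Wnt/beta-catenin targets, 10 fell and 1 rose (median -1.75, camera adjusted p = 8.51e-05; adjusted p = 0.0994 with an estimated correlation). Axin2, a feedback inhibitor of the pathway, fell from 273.4 ± 71.2 to 24.0 ± 3.32 CPM and Ephb3, a receptor of the crypt base, from 78.0 ± 11.9 to 10.6 ± 1.62 CPM. The target that rose, singled out after its values were seen, was the cyclin gene Ccnd1 (299.2 ± 50.9 to 676.0 ± 79.3 CPM).

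Of 20 proliferation genes, 17 fell and 0 rose (median log2 fold change -2.08, camera adjusted p = 2.57e-07; adjusted p = 0.138 with an estimated correlation), and 19 fell without control replicate 3. The mitotic kinase gene Plk1 fell from 96.9 ± 4.14 to 17.4 ± 2.08 CPM, Ccna2 (cyclin A) from 180.5 ± 40.9 to 46.0 ± 2.00 CPM and the thymidylate synthase gene Tyms from 27.5 ± 1.28 to 6.90 ± 1.01 CPM. Mki67 had 618.9 ± 398 and 222.8 ± 32.6 CPM and did not pass (log2 change -1.47, adjusted p = 0.0727; -1.91 and 7.40e-10 without control replicate 3). The other members that did not pass, named after their values were seen, were Cdc20 (93.1 ± 44.2 and 61.1 ± 2.66 CPM) and Pcna (99.8 ± 12.2 and 101.4 ± 8.97 CPM). Without control replicate 3, Cdc20 passed (adjusted p = 9.02e-09).

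All 12 measured Paneth cell markers fell, with a median log2 fold change of -6.81, or -6.26 with the 4 genes at 0 counts in all doxycycline libraries set at their bound (camera adjusted p = 9.53e-08; adjusted p = 0.176 with an estimated correlation). Lyz1 (chromosome 10, 117287795 to 117292868) fell by 6.35 on the log2 scale (SE 0.344, adjusted p = 6.27e-05). The antimicrobial gene Ang4 fell from 213.6 ± 116 to 0.370 ± 0.355 CPM, the lectin gene Itln1 from 141.3 ± 108 to 0.733 ± 0.352 CPM and the defensin gene Defa24 from 187.2 ± 87.7 to 3.77 ± 0.715 CPM. The log2 change of Ang4 was -9.05, and -10.02 without doxycycline replicate 3; that of Itln1 was -7.52, and -6.65 without control replicate 3. Alpha-defensin genes are close copies of each other, so their separate values are uncertain. Of 13 goblet cell markers, 12 fell (median -4.78, the same with 4 genes at their bound; camera adjusted p = 1.21e-06; adjusted p = 0.0892 with an estimated correlation). The median was -3.84 without control replicate 3 and -5.71 without doxycycline replicate 1. Atoh1, the transcription factor of secretory fate, was at least 420-fold lower and Spdef, which acts in goblet cells, at least 209-fold lower (249.6-fold and 124.4-fold without doxycycline replicate 3). The mucin gene Muc2 fell from 13.1 ± 8.91 to 0.277 ± 0.199 CPM, a log2 change of -5.58 that was -4.87 without control replicate 3 and -6.25 without doxycycline replicate 1. Fcgbp, singled out after its values were seen, was the member that did not pass (927.8 ± 574 and 1053 ± 204 CPM, adjusted p = 0.807).

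Of 13 enteroendocrine markers, 11 fell and 0 rose (median log2 fold change -2.39, camera adjusted p = 2.23e-05; adjusted p = 0.0814 with an estimated correlation), and 13 fell adjusted over the list alone. Without control replicate 3 the median was -1.85 over the 16 members then measured, of which 14 fell. The granule protein gene Chga fell from 51.4 ± 16.7 to 14.7 ± 2.16 CPM. Neurog3, the transcription factor of endocrine progenitors, had 1159 counts over the control libraries and 2 over the doxycycline libraries, a ratio of 504.5 after scaling (95% interval 139 to 4171). It was at least 232-fold lower without doxycycline replicate 2, which held both counts, and the ratio was 299.7 without doxycycline replicate 3. Insm1 fell from 25.8 ± 7.91 to 2.32 ± 0.889 CPM. Chgb (334.7 ± 133 and 177.5 ± 15.4 CPM) and Neurod1 (9.28 ± 4.83 and 3.85 ± 0.468 CPM), named after their values were seen, had adjusted p of 0.0518 and 0.0538, and of 1.13e-10 and 1.38e-06 without control replicate 3. Tuft cell markers went both ways, with 3 of 11 higher and 4 lower (median -0.52, camera adjusted p = 0.472, fry adjusted p = 0.0158). Dclk1 had 9.15 ± 3.87 and 14.8 ± 1.46 CPM (adjusted p = 0.138; 0.0371 without control replicate 3). Ptgs1, a cyclooxygenase gene, rose from 1.04 ± 0.574 to 10.1 ± 1.51 CPM, while Hpgds, a prostaglandin D synthase gene, fell from 3.91 ± 1.06 to 0.959 ± 0.0962 CPM and Alox5ap from 2.07 ± 1.17 CPM to 0 counts, at least 22.1-fold lower (13.1-fold without doxycycline replicate 3). Ltc4s fell from 1.71 ± 0.304 to 0.275 ± 0.151 CPM. Another 2 members were singled out after their values were seen. Alox5 rose (0.331 ± 0.240 to 1.34 ± 0.442 CPM; log2 change 2.08, and 2.70 without control replicate 3), and Pou2f3, the transcription factor of tuft cells, fell (3.60 ± 0.651 to 1.56 ± 0.608 CPM). Their calls were lost with 5 and 3 of the 6 single libraries left out, at adjusted p of up to 0.0956 and 0.1225.

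Of 22 enterocyte markers, 12 rose and 1 fell (median log2 fold change 1.11, camera adjusted p = 1.91e-04; adjusted p = 0.176 with an estimated correlation). Without control replicate 3, 19 rose and 2 fell. Alpi, the intestinal alkaline phosphatase of the brush border, rose from 1021 ± 279 to 6055 ± 189 CPM (log2 change 2.57, SE 0.233, adjusted p = 2.96e-04). Anpep, a brush border peptidase, rose from 172.9 ± 9.46 to 1529 ± 245 CPM and the peptide transporter gene Slc15a1 from 10.4 ± 1.07 to 56.5 ± 2.59 CPM. Krt20, a keratin of differentiated epithelium, rose by 4.60 on the log2 scale (SE 0.174). Fabp1 rose from 12.1 ± 1.40 to 21.3 ± 3.17 CPM (adjusted p = 0.0145), a call lost with total counts (0.156) and without control replicate 2 (0.0528), doxycycline replicate 1 (0.0517) or doxycycline replicate 3 (0.0716). Treh, a disaccharidase gene singled out after its values were seen, fell from 15.9 ± 6.08 to 3.20 ± 1.01 CPM.

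Of 16 p53 target genes, 9 rose and 0 fell (median log2 fold change 0.91, camera adjusted p = 5.39e-04; adjusted p = 0.0892 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a rose from 230.9 ± 36.9 to 1324 ± 88.6 CPM, the kinase gene Plk2 from 10.4 ± 0.449 to 91.8 ± 7.92 CPM and the desmosome-associated gene Perp from 228.2 ± 4.76 to 742.4 ± 22.3 CPM. Of 9 AP-1 subunits, 7 rose and 0 fell, and 8 rose adjusted over the list alone (median 1.60, camera adjusted p = 4.77e-05; adjusted p = 0.0892 with an estimated correlation). Fos rose from 17.3 ± 0.488 to 288.8 ± 13.1 CPM, Atf3 from 24.3 ± 6.50 to 144.4 ± 18.8 CPM and Junb from 154.1 ± 7.95 to 466.8 ± 22.6 CPM. Of 13 EGFR ligands and ERK feedback genes, 8 rose and 2 fell (median 1.15, camera adjusted p = 0.00903; adjusted p = 0.217 with an estimated correlation). The ligand genes Areg (14.8 ± 2.36 to 78.2 ± 2.87 CPM) and Hbegf (15.5 ± 1.08 to 76.3 ± 5.88 CPM) and the ERK phosphatase gene Dusp5 (78.5 ± 1.53 to 350.3 ± 10.8 CPM) rose. The ETS transcription factor gene Etv5 fell from 39.5 ± 2.35 to 10.2 ± 1.14 CPM, and so did Etv4, singled out after its values were seen (54.1 ± 24.6 to 4.05 ± 1.14 CPM).

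Of 21 adhesion, matrix and actin genes, 13 rose and 3 fell, and 15 rose adjusted over the list alone (median log2 fold change 1.17, camera adjusted p = 1.91e-04; adjusted p = 0.0892 with an estimated correlation). The basement membrane genes Col4a2 (2.35 ± 0.584 to 85.2 ± 11.8 CPM) and Lama3 (0.204 ± 0.115 to 8.90 ± 1.12 CPM) rose. The 3 members that fell were named after their values were seen. The myosin light chain gene Myl9 went from 4.91 ± 3.61 CPM to 0 counts, at least 51.4-fold lower (33.6-fold without control replicate 3 and 30.5-fold without doxycycline replicate 3). The integrin genes Itga2 (81.0 ± 30.2 to 42.0 ± 1.78 CPM) and Itga5 (2.46 ± 1.09 to 0.682 ± 0.165 CPM) lost their calls with any doxycycline library left out (adjusted p = 0.0526 to 0.123), and Itga2 also without control replicate 1 (0.0921) or 2 (0.102) and with limma-voom (0.0541).

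Of 18 cholesterol synthesis genes, 11 rose and 1 fell (median log2 fold change 0.85, camera adjusted p = 8.16e-04; adjusted p = 0.0814 with an estimated correlation), and 17 rose without control replicate 3. The synthase gene Hmgcs1 rose from 712.4 ± 121 to 1731 ± 20.8 CPM and Cyp51 from 466.5 ± 29.6 to 904.4 ± 19.7 CPM. Of 16 interferon-stimulated genes, 10 rose and 0 fell (median 1.12, camera adjusted p = 8.06e-04; adjusted p = 0.0892 with an estimated correlation), at low levels such as 0.563 ± 0.0822 to 5.27 ± 1.32 CPM for Mx1 and 1.36 ± 0.182 to 10.4 ± 3.83 CPM for Rsad2.

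Of 10 NF-kB and chemokine genes, 2 rose and 1 fell (median log2 fold change 0.06, camera adjusted p = 0.472, fry adjusted p = 0.00681), and 4 rose without control replicate 3. The median was -0.38 with total counts as the scaling. Cxcl16 rose from 23.1 ± 4.51 to 211.3 ± 14.9 CPM, Tnfaip3 rose from 18.2 ± 5.17 to 73.5 ± 5.64 CPM and Icam1 fell from 2.92 ± 1.32 to 0.341 ± 0.219 CPM. Of 17 integrated stress response genes, 5 rose and 2 fell (median 0.30, camera adjusted p = 0.186), and without control replicate 3, 11 rose and the adjusted p was 0.0454 (0.578 over all libraries with an estimated correlation). Ddit3 was at 33.4 ± 17.5 and 98.3 ± 10.4 CPM (adjusted p = 0.012). With total counts some of the stress response genes that rose lost their calls (edgeR adjusted p = 0.0726 to 0.0976). The 2 that fell lost theirs without doxycycline replicate 2 or 3 (0.0758 to 0.0925). Of 20 nuclear genes of oxidative phosphorylation, 1 rose and 0 fell (median 0.04, camera adjusted p = 0.453), and without control replicate 3, 10 rose and the list was called (adjusted p = 0.0185; 0.727 over all libraries with an estimated correlation). That gene was Cox5a (1.94 ± 0.873 to 5.17 ± 0.829 CPM), whose call was lost with total counts and without control replicate 1, doxycycline replicate 2 or doxycycline replicate 3 (adjusted p = 0.0578 to 0.0816), and no member passed adjusted over the list alone. The medians of the stress response and oxidative phosphorylation lists were -0.15 and -0.40 with total counts as the scaling.

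Markers of other cell types were sparse. Of the mesenchymal, MHC class II, endothelial, gastric and immune lists, 1, 1, 2, 3 and 4 members were measured, too few for a list test. Vim, an intermediate filament gene of mesenchymal cells, fell from 4.86 ± 1.28 to 0.826 ± 0.272 CPM. H2-DMa had 10.3 ± 7.76 and 11.2 ± 1.49 CPM (adjusted p = 0.91). Among immune markers, Laptm5 rose from 1.09 ± 0.938 to 21.6 ± 1.66 CPM (log2 change 4.28, and 5.20 without control replicate 2), while Csf1r (26.8 ± 12.04 and 25.1 ± 0.525 CPM), Cd68 (2.54 ± 1.203 and 1.82 ± 0.589 CPM) and Itgam (2.80 ± 0.298 and 3.38 ± 1.12 CPM) did not pass; Csf1r passed as higher without control replicate 3 (log2 change 0.34, adjusted p = 0.0252). Of the gastric markers, Anxa10 (29.1 ± 10.9 to 84.9 ± 3.97 CPM) and the mucin gene Muc6 (1.76 ± 0.886 to 7.11 ± 1.82 CPM) rose. Cldn18 fell (2.96 ± 0.875 to 0.552 ± 0.501 CPM), a call lost without control replicate 2, doxycycline replicate 1 or doxycycline replicate 3 (adjusted p = 0.0528 to 0.0768); its log2 change of -2.46 was -3.48 without doxycycline replicate 2. The endothelial receptor gene Tek rose from 0.427 ± 0.160 to 1.40 ± 0.277 CPM, a call lost without control replicate 1 or 2 or doxycycline replicate 2 or 3 (adjusted p = 0.0568 to 0.068), and Eng had 1.59 ± 0.903 and 1.15 ± 0.251 CPM (adjusted p = 0.486).

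Of the 10 genes ranked highest by fitted rise, Cavin2, a caveola protein gene at 0 counts in all control libraries, had 152.8 ± 10.3 CPM with doxycycline and was at least 2055-fold higher, and Stk32c was at least 237-fold higher. Loxl4, a lysyl oxidase gene, had 2 counts in the control libraries and 2614 with doxycycline, a ratio of 1501 after scaling (95% interval 415 to 12400). Without control replicate 2, which held both control counts, it was at least 675.9-fold higher. Without control replicate 1 the bounds of Cavin2 and Stk32c and the ratio of Loxl4 were 0.573 of those given. The myelin and epithelial membrane gene Pmp22 rose from 0.739 ± 0.493 to 808.7 ± 24.6 CPM and Clca4a from 0.448 ± 0.254 to 328.4 ± 14.8 CPM. The others were Crct1, a cornified envelope gene, Hyal5, Serpinb6b, Ly6m and Pbp2, with log2 changes of 7.44 to 8.31. All 4 control counts of Crct1 were in control replicate 3, without which it was at least 359-fold higher. Without that library the log2 change of Serpinb6b went from 7.64 to 8.84. Hyal5, with a log2 change of 8.09 over all libraries, then had 1 control count, a ratio of 1133 after scaling (95% interval 203 to 44780). Without control replicate 1 the log2 changes of Crct1, Hyal5 and Serpinb6b were 7.57, 7.35 and 6.90. The 10 genes ranked highest by fitted fall were all at 0 counts in the doxycycline libraries. Their bounds do not show that they fell more than genes with counts such as Olfm4 (652.6-fold lower). Besides Atoh1 and Spdef these 10 were Prelp, a matrix proteoglycan gene (at least 296-fold lower), Cttnbp2 (193-fold), the Wnt ligand gene Wnt3 (158-fold, 13.6 ± 1.14 CPM in control) and the Paneth cell genes Mptx2 (227-fold), Pla2g2a (153-fold), Defa39 (291-fold), Defa29 (139-fold) and Defa38 (141-fold). Without doxycycline replicate 3 all of these bounds were 0.594 of those given, and without control replicate 3 those of Mptx2, Pla2g2a, Defa39 and Defa29 were 149.4, 93.0, 183.4 and 89.95. Pla2g2a is annotated as a transcribed pseudogene in RefSeq's gene table.

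Camera with the preset correlation called 16 of the 20 lists tested, 10 higher and 6 lower, and fry called 18. With an estimated correlation 1 list was called, that of crypt base columnar stem cells. Camera with the preset correlation also called 9 to 14 lists when the 6 libraries were divided in the 9 other ways into 3 and 3. Those divisions held both treatments on each side in unequal numbers, so part of the treatment difference remained. The 9 to 14 lists are therefore not a rate of false calls. Where no count adjusted over the list alone is given, it equalled the count over all genes, except 13 higher for enterocyte markers and 18 lower for proliferation genes.

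**Figure D3:**
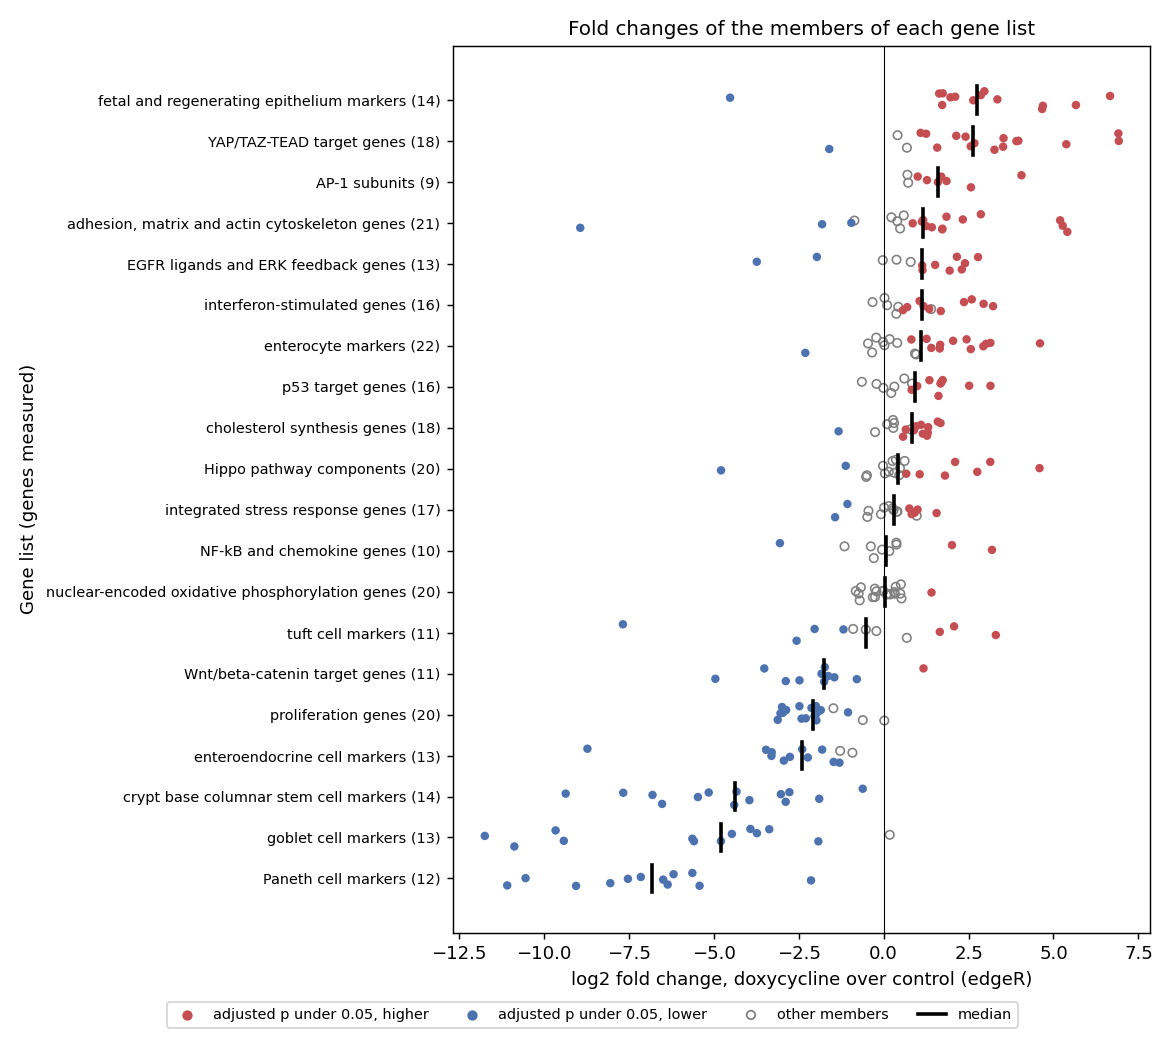
Log2 fold change (doxycycline over control) of each measured member of the 20 lists tested, ordered by list median (bar). Filled points had an edgeR adjusted p under 0.05 (red, higher; blue, lower); the medians ran from -6.81 for Paneth cell markers to 2.75 for fetal and regenerating epithelium markers.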

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

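The length trend and the library weights were added as settings after the data were seen; the others were fixed before. Over 84 recomputed counts, 67 stayed within 1.5 times the reported value and 17 moved further. With library weights in limma-voom 9540 genes were called (4665 higher, 4875 lower), and at an adjusted p under 0.01, 3477 (1780 higher, 1697 lower). With total counts 1747 were higher and 5131 lower. The test against a 2-fold change called 2112 genes in place of 4238. With single libraries left out, calls ran from 3836 without doxycycline replicate 3 to 9286 without control replicate 3 (1945 to 4632 higher, 1888 to 4654 lower). The spread between libraries (biological coefficient of variation) was 0.268 with control replicate 3 and 0.0832 without it. Explanations for the difference of that library are taken up below, and other causes of the moved counts were not tested. With an estimated correlation 1 list was called in place of 16, and the adjusted p was 0.0814 for YAP/TAZ-TEAD targets and 0.0676 for fetal and regenerating markers. Over the 20 lists, 279 of 300 recomputed results kept the direction given by the list test and the side of the threshold, and 0 reversed. Camera's direction is relative to the other genes, and the medians of some lists turned sign with total counts, as given above.

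The log2 fold change of Yap1 passed the threshold at -0.96 with total counts, -0.60 with the length trend removed and -0.66 with library weights; it ran from -0.67 (passing, without control replicate 3) to -0.41 with single libraries left out. For the 119 genes named by the rule, 1844 results stayed the same, 29 lost a call (8 genes), 21 gained one (6 genes) and 10 turned direction (5 genes). For the 35 genes singled out later, 499 stayed, 41 lost a call (9 genes), 13 gained one (3 genes) and 7 turned (2 genes). None of the genes that turned had passed the threshold. With total counts the log2 fold change was -0.26 for Fcgbp, -0.33 for H2-DMa, -0.18 for Itgam, -0.42 for Pcna and -0.0618 for Sod2. With library weights it was 0.31 for Csf1r, -0.16 for Fcgbp and -0.31 for H2-DMa, and with plain limma-voom 0.0178 for Csf1r. With single libraries left out it ran from -0.30 to 0.34 for Csf1r, -0.72 to 0.071 for Eng, -0.24 to 0.49 for Fcgbp, -0.38 to 0.49 for H2-DMa, -0.0221 to 0.46 for Itgam and -0.0392 to 0.14 for Pcna. The cause was not tested, except that total counts shift the median of all genes to -0.53.

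With the replicate number as a block 4509 genes were called (2261 higher, 2248 lower; 3851 at least 2-fold) and 16 lists, and Yap1 did not pass. Of the named genes 8 lost their call with the block. Among them were Amot, Itga2, Alox5, Pou2f3, Tek and Cox5a (edgeR adjusted p = 0.0507 to 0.0869). The numbers were not taken as pairs because the labels do not say that equal numbers mark a shared culture. Deviations of libraries with the same number correlated at -0.30, 0.12 and -0.19, and no library correlated best with its own number. Those of control replicate 3 correlated at -0.899 and -0.892 with the other control libraries and dominated that group, so these values cannot exclude pairing. In simulated counts 14% of 2-fold changes were recovered, but far fewer genes were changed there than were called in the data. No simulated library stood apart as control replicate 3 did. Small changes may be missed, at a share that the simulation does not give.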

Other observations

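The genes of the next paragraphs, the gene families and the tests on control replicate 3, the protocadherins and the ribosomal protein genes were chosen after the results were seen. The other divisions of the samples were fixed before.

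Of genes outside the lists, the ligand gene Bmp2 rose from 12.3 ± 5.26 to 432.9 ± 50.7 CPM, and the genes Id1 (40.6 ± 6.60 to 469.8 ± 10.2 CPM), Id3 (15.03 ± 3.92 to 284.9 ± 17.2 CPM) and Smad7 (14.8 ± 5.85 to 186.7 ± 15.2 CPM) rose too. Of 8 genes with the Bmp stem, 3 rose and 3 fell (camera adjusted p = 0.761). Klf4, a transcription factor of differentiated cells, rose from 46.2 ± 10.2 to 940.7 ± 44.4 CPM, Hnf4a from 1539 ± 318 to 3514 ± 184 CPM and the membrane protein gene Emp1 from 187.0 ± 50.2 to 5450 ± 135 CPM. Sox4 fell from 609.8 ± 123 to 17.4 ± 1.17 CPM and the intestinal homeobox gene Cdx1 from 292.6 ± 60.1 to 16.5 ± 0.91 CPM. Trp53, which encodes p53, fell from 122.9 ± 70.8 to 27.8 ± 5.13 CPM (log2 change -2.15, and -1.56 without control replicate 3) while 9 of 16 of its targets rose. The apolipoprotein genes Apob (1475 ± 790 to 11280 ± 2854 CPM) and Apoa1 (808.9 ± 361 to 6535 ± 85.4 CPM) were among the most abundant that rose, and both belong to the enterocyte list.

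Genes grouped by the stem of their symbols gave 198 families of at least 8 members, of which camera with the preset correlation called 33 (11 higher, 22 lower) and 0 with an estimated correlation (adjusted p of 0.631 or more). Of 15 keratin genes 12 rose and 1 fell (median log2 fold change 2.90, 2.46 with total counts; adjusted p = 1.36e-04, 0.631 with an estimated correlation). Krt19 rose from 1607 ± 137 to 8879 ± 302 CPM, Krt8 from 730.6 ± 318 to 4691 ± 294 CPM and Krt18 from 261.5 ± 106 to 1953 ± 80.6 CPM. Krt14, a keratin of basal cells in stratified epithelia, had 0 counts in the control libraries and 6.13 ± 0.557 CPM with doxycycline, at least 81.2-fold higher (46.5-fold without control replicate 1). Of 10 Mcm genes, most of them replication helicase subunits, 8 fell, and so did all 10 measured Exosc genes of the RNA exosome (medians -2.81 and -1.73; adjusted p = 0.0032 and 0.00247; both 0.631 with an estimated correlation). Of 14 Snhg genes, hosts of small nucleolar RNAs, 11 fell (median -1.37, adjusted p = 0.00247; 0.631 with an estimated correlation). Each of these medians kept its sign with RLE factors and with total counts.

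Control replicate 3 differed from control replicates 1 and 2 more than any other libraries of a group differed, with a mean SD of log2 differences of 0.922 over 10258 genes. Its deviation fell with transcript length across genes, which are not independent replicates (Spearman's rho -0.53), but with that trend removed the SD was still 0.796 against a highest of 0.285 for other pairs, so length is not the whole cause. With all libraries thinned to its depth, the highest SD of other pairs was 0.312 against 0.917 for its own pairs, which argues against depth. It was also compared over 7 genes that were abundant with doxycycline and chosen for near absence from control replicates 1 and 2. Its median CPM was 0.306% of the doxycycline mean. In the other control libraries the median was up to 0.245%, a value kept low by that choice. In control replicate 3, Tmem151a (2.24%) and Serpinb6b (1.24%) were above 1% and the others below. For these genes the median argues against a wrong label or a mixture of 1% or more. A difference in culture or handling of this library remains open and no biological explanation was tested.

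All 12 measured Pcdha genes rose and all 12 Pcdhga genes fell (median log2 fold change 4.98 and -1.38; 4.58 and -1.82 with total counts). Of the 12 Pcdha genes, 11 held the same 6 counts (0, 2, 0, 27, 14 and 24), while sets of 12 other genes of a like level held a median of 12 different sets of counts among 1000 random sets. This is consistent with reads of the exons that the genes of a cluster share being counted for each gene, and it argues against separate changes of the Pcdha genes. The Pcdhga genes held 12 different but close sets of counts. Each cluster may therefore stand for 1 measurement of its shared exons.

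Ribosomal protein genes had low and uneven counts for genes of their kind, from 0.831 (Rpl38) to 336 (Rpl4) mean CPM by total counts over 75 genes, with a median of 15. Across these genes the level rose with the longest exon (Spearman's rho 0.362, two-sided permutation p = 0.00131, adjusted p = 0.00262 over 2 relations), and for the share of sequence found in no other gene rho was 0.182 (p = 0.119). The bound of 0.5 on rho that would have counted for either explanation was set after these values had been seen, so neither short exons nor shared sequence is settled by it; the association with exon length also leaves true differences in level open. Of 9 copies, recognised by symbol alone, with a parent gene in the table, 5 had more counts than the parent. Examples were Rpl37rt with 995 CPM against 5.55 for Rpl37 and Rplp2-ps1 with 648 against 7.79 for Rplp2. By symbol stem, 21 of 48 Rpl genes and 21 of 44 Rps genes fell, and 3 Rps genes rose. Without control replicate 3, 37 Rpl and 29 Rps genes fell and 6 Rps genes rose. These stems also take in symbols outside the 75 genes, so the counts are not of ribosomal protein genes alone. The falls of ribosomal protein genes rest on counts that may be split between copies, and no biological explanation was tested. Whether genes outside this group were also counted low was not tested. Values such as those of Fabp1 (12.1 ± 1.40 CPM in control) and Cox5a (1.94 ± 0.873 CPM in control) therefore need not be true levels.

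Of the 10 divisions of the 6 libraries into 3 and 3, 1 gave as many genes as the 5850 called, namely the real one, and the highest of the others was 0. The same held for the 2800 higher, the 3050 lower and the 4238 at least 2-fold, each with 0 as the highest of the others by edgeR. For gene lists the real value was 16 and the highest other 14, and for families 33 and 29. These divisions are too few for a share under 0.05. Each of the others mixed the treatments on both sides. The treatment difference then adds to the spread within sides, so 0 genes called by edgeR there does not measure chance. Part of that difference also stays between the sides, so the list and family counts are not rates of false calls.

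Among counts of 1 to 20, 58.7 to 66.4% were even in each library, and more genes had 2 counts than 1 in all 6 libraries, for example 861 against 467 in control replicate 1. The cause was not tested. The bounds and binomial intervals given above take each count as independent. If counts often came in pairs, the bounds would be too high and the intervals too narrow.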
